A study of Mus musculus with 5 samples.

How the data were processed

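β-catenin occupancy was profiled by ChIP-seq in V6.5 mouse embryonic stem cells that carry a biotin and triple-FLAG tag knocked into Ctnnb1, the gene that encodes β-catenin. Per the labels, the tagged protein was captured through FLAG or through streptavidin. The 5 samples are 3 ChIP libraries and 2 input libraries, and each stands alone in its group. The input libraries entered only as the controls of the authors' peak calls and were not analysed here on their own.

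The deposited peak tables were made with MACS from ELAND-format alignments, 1 ChIP library against 1 input library at a time, per the file headers. The MACS version is not given in the sources used here. Per the file headers, all 3 runs used a p-value cutoff of 1.00e-05, an effective genome size of 1.87e+09, a tag size of 25 bp and a band width of 300 bp. The value d of MACS, called the fragment shift here, was 185 bp for CHIR99021 anti-FLAG, 214 bp for CHIR99021 streptavidin and 30 bp for DMSO, per the file headers. The model fold setting was 20, 32 and 20, in that order. The genome build was mm9, per the submitters' processing notes. On 10 chromosomes the last deposited peak ended beyond the last gene of GRCm38, the build of the only gene table at hand. Peaks were therefore named by their mm9 coordinates, and no gene, exon or motif was assigned to them. The planned results on genomic location, gene lists and motifs were not run.

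Each deposited row gives a peak's interval, its tag count, a p score, a fold ratio over the local background and a false discovery rate in percent, per the file headers. The tag count is a whole number of tags in the peak. The p score is 10 times −log10 of the p-value, so the cutoff corresponds to a score of 50. The fold ratio and the score are the authors' values for single peaks. They were used only to describe, rank or filter peaks within their own list, because the libraries differ in depth and in the shift. P scores reached a ceiling near 3100, which leaves ties among the strongest peaks. The 2 deposited interval files for CHIR99021 repeated the MACS intervals row for row. The one for DMSO held windows of 400 bp around the summits, and the MACS intervals were used in the main results.

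Per the file headers, the anti-FLAG library had 16100920 unique tags of 24829905, and the CHIR99021 streptavidin library had 11934863 unique tags of 19210345. Their shared input had 17758366 unique tags of 33912075. The header of the DMSO table gives no tag totals, so the depth of that library and of its input is unknown. The labels and the header name streptavidin or biotin as the capture for the DMSO library, whereas the names of the run and the file say FLAG. The label was followed, and the DMSO list was compared with both CHIR99021 lists. The labels' protocol gives 16 hours of treatment at 3 µM, and the series text gives 24 hours.

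Peaks were taken as shared when they had at least 1 bp in common. Shares carry 95% exact (Clopper-Pearson) intervals over peaks. These cover counting error only and say nothing about a repeat of the experiment. A chance share was taken from 1000 random circular shifts of a list within its chromosomes' spans, as a description, and no p-value is given. The shifts take no account of open chromatin or of where reads can be mapped. A share above chance therefore does not show that sites are specific to β-catenin. No ChIP from cells without the tag was among the samples. Overlapping or touching peaks of the 3 lists were merged into regions. Lists were cut into 10 equal parts by p score. Peaks per Mb used the span between the first and last peak of each chromosome over all lists. Named regions followed a fixed rule. It took the 10 regions with the smallest sum of within-list ranks by p score among those of both CHIR99021 lists, of both without a DMSO peak, of DMSO alone and of all 3 lists. Ties in rank, which the ceiling of the p score makes common among the strongest peaks, were broken by coordinate. With 1 library per group, no test across samples was possible, and spread between replicates could not be measured.

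Groups, comparisons, alternatives and the naming rule were set before the data were examined. The alternatives changed the overlap rule, the peak threshold, the list lengths, the chromosomes, the ranking and the chance model. Others were added after seeing the data and are named as such. The overlap code was tested on simulated lists: it recovered 1500 of 1500 planted shared peaks. There the chance share by circular shifts was 5.21%, against 4.75% by formula. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.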

Results

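β-Catenin, the transcriptional effector of canonical Wnt signalling, was mapped on chromatin in mouse embryonic stem cells grown in serum and LIF on feeder cells. CHIR99021 inhibits GSK3, the kinase that marks β-catenin for degradation, and DMSO was the vehicle control. Cells carried a tag on endogenous β-catenin with a FLAG epitope and a site that the BirA enzyme biotinylates. Chromatin of 10000000 cells was used per ChIP. There were 3 ChIP libraries with deposited peaks: CHIR99021 captured by anti-FLAG, CHIR99021 captured by streptavidin, and DMSO captured by streptavidin. The DMSO capture is given as labelled, although its run was named for FLAG. Each was the only library of its group, so no value below has a replicate error.

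The anti-FLAG list held 16069 peaks, the CHIR99021 streptavidin list 15947 and the DMSO list 12734. Peaks of both CHIR99021 lists were of similar size. Their median lengths were 859 and 926 bp, their median tag counts 39 and 34, and their median fold enrichments 8.13 and 8.56. DMSO peaks had a median length of 74 bp and a median of 6 tags. Of them, 9083 (71.3%) held exactly 6 tags, the smallest count in the list, and 186 held 20 or more. In the CHIR99021 lists 85.5% of anti-FLAG and 78.8% of streptavidin peaks held 20 or more tags. DMSO peaks covered 0.980 Mb in all, against 15.4 Mb for anti-FLAG and 16.5 Mb for CHIR99021 streptavidin. The DMSO list was called with a fragment shift of 30 bp, shorter than for the other lists, so its peak number and lengths are not comparable with those of the other lists. Peaks took up 5.65% of the unique anti-FLAG tags and 6.60% of the unique CHIR99021 streptavidin tags. The depth of the DMSO library is unknown. At an FDR of at most 1%, 10417 anti-FLAG, 8832 CHIR99021 streptavidin and 14 DMSO peaks were left.

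**Figure D1:**
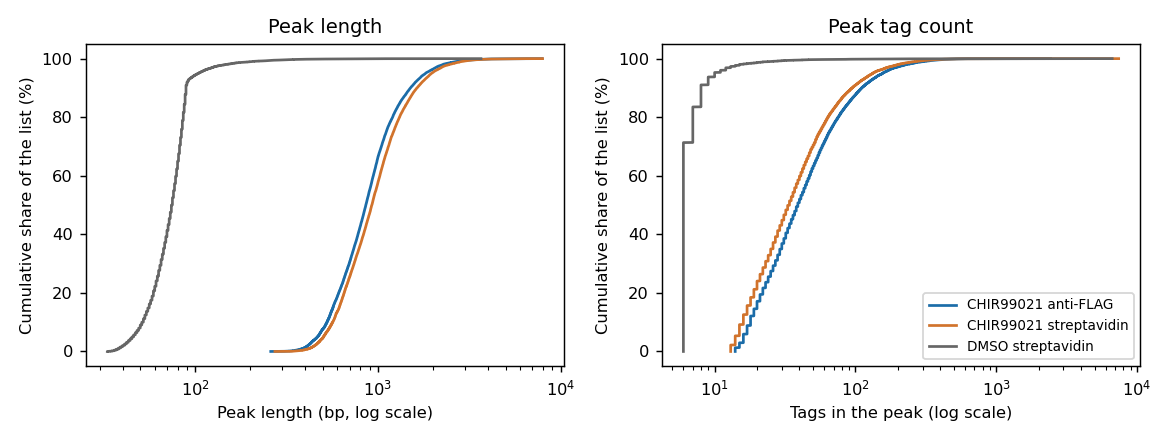
Cumulative share of each list (percent) by peak length (bp, log scale, left) and by tags in the peak (log scale, right), 1 line per ChIP library. The DMSO line lies left of both CHIR99021 lines, with a median length of 74 bp against 859 and 926 bp.

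The first comparison asked whether capture through FLAG and capture through biotin found the same sites in CHIR99021-treated cells. The strongest sites were found by both. By p score, regions on chromosome 2 (135440051 to 135441977) and chromosome 15 (65580614 to 65582519) ranked highest in the 2 lists together, in mm9 coordinates as throughout. Their lead rests on scores of 3230.05 and 3225.28 in 1 list each. The other named regions, first chromosome 4 (64899369 to 64900379), tied at 3100 in both lists. In all, 21 anti-FLAG and 22 streptavidin peaks lay at or near this ceiling. Coordinates alone decided which tied regions are named. An equally ranked region on chromosome 14 (22962757 to 22964162), with fold enrichments of 178.86 and 221.11, was left out for that reason. The region on chromosome 2 had a fold enrichment of 100.93 by anti-FLAG and 110.75 by streptavidin, from 412 and 362 tags. That on chromosome 15 had 90.85 and 116.44, from 332 and 355 tags. That on chromosome 4 had 64.28 and 81.99, from 418 and 378 tags. The other named regions lay on chromosome 4 (107404976 to 107407757 and 129427137 to 129428770), chromosome 5 (28156806 to 28157653), chromosome 7 (6208976 to 6212323) and chromosome 9 (69514870 to 69519669, 94559442 to 94563343 and 97376186 to 97378720). Over the 10 regions, fold enrichment ranged from 37.3 to 132.7 by anti-FLAG and from 40.0 to 141.8 by streptavidin. Of these, the one on chromosome 9 from 94559442 had the most tags with 1223 and 1207.

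Across the whole lists, 9255 of 16069 anti-FLAG peaks (57.6%, interval 56.8 to 58.4%) shared bases with a CHIR99021 streptavidin peak. In the other direction it was 9216 of 15947 (57.8%, interval 57.0 to 58.6%). Random shifts of the anti-FLAG list gave 1.28% on average and at most 2.79%. Where peaks overlapped, the summits lay a median of 42 bp apart. The share fell with rank. Of the top 10% of anti-FLAG peaks by p score, 98.4% (interval 97.6 to 98.9%) lay in a streptavidin peak, and of the lowest 10% it was 17.5% (15.7 to 19.5%). That lowest share depended on the ranking, with 35.9% by fold enrichment and 8.77% by tag count. In the streptavidin list the top 10% reached 99.9% (99.7 to 100.0%) and the lowest 10% reached 18.2% (16.4 to 20.2%). Here too the lowest share depended on the ranking, with 30.5% by fold enrichment and 12.0% by tag count. In the top 10%, 26 anti-FLAG peaks lacked a CHIR99021 streptavidin partner, led by chromosome 12 (44073587 to 44074415, 159 tags, fold enrichment 60.12) and chromosome 12 (25109804 to 25110509, 120 tags, fold enrichment 64.66). Some of the 26 did overlap a DMSO peak, such as those on chromosome 2 (33945858 to 33946658) and chromosome 13 (55071850 to 55072844). These were named after their values were seen. The only CHIR99021 streptavidin peak of the top 10% without an anti-FLAG partner lay on chromosome 1 (24618181 to 24623212), with 7407 tags and a fold enrichment of 1.67. It overlapped a DMSO peak. With fold enrichment of at least 10 in both lists, the shared portion of anti-FLAG peaks was 74.2%.

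**Figure D2:**
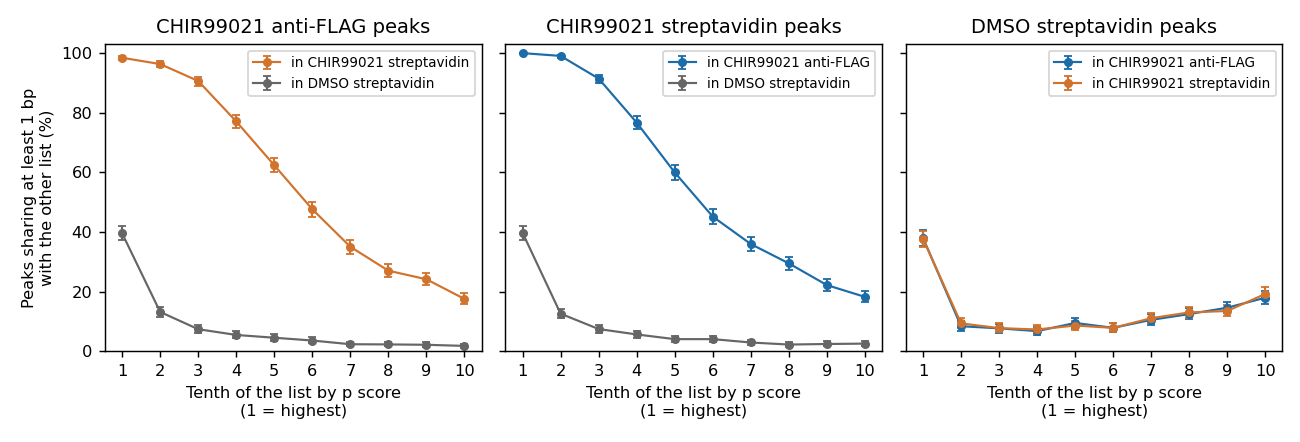
Percent of peaks that share at least 1 bp with another list (y axis) in each successive 10% of a list by p score (x axis, 1 is the highest), 1 panel per list. Bars are 95% exact binomial intervals over peaks. Overlap between the CHIR99021 lists runs from 98.4% and 99.9% down to 17.5% and 18.2%, and overlap of their top 10% with the DMSO list is 39.5% and 39.7%. Overlap of DMSO peaks with CHIR99021 streptavidin peaks falls from 37.7% in the first 10% to 9.35% in the second and 7.31% in the fourth. It then rises to 19.2% in the last.

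The second comparison set CHIR99021 against DMSO. The strongest regions of CHIR99021-treated cells also held DMSO peaks: this was so for 10 of the 10 regions named for the 2 CHIR99021 lists. On chromosome 9, the region from 94559442 to 94563343 held 2 DMSO peaks with 141 tags, the leading one at rank 12 of the DMSO list. The one from 69514870 to 69519669 held 2 with 100 tags, at rank 15. On chromosome 4, the region from 107404976 to 107407757 held 2 with 21 tags, at rank 789. Outside these regions, most CHIR99021 peaks held none, and fewer of the weaker peaks by p score held one. Of the top 10% of CHIR99021 streptavidin peaks, 39.7% (interval 37.3 to 42.2%) contained a DMSO peak, and of the lowest 10% it was 2.57% (1.85 to 3.47%). For anti-FLAG the shares were 39.5% (37.1 to 42.0%) and 1.80% (1.21 to 2.58%). The lowest shares depended on the ranking. By fold enrichment they were 5.20% for CHIR99021 streptavidin and 4.29% for anti-FLAG, and by tag count 1.00% and 0.747%. Across the whole CHIR99021 streptavidin and anti-FLAG lists, 8.38% and 8.24% of peaks held a DMSO peak. Random shifts gave 0.571% and 0.531% on average.

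Over the whole lists, 1725 of 12734 DMSO peaks (13.5%, interval 13.0 to 14.2%) lay in a CHIR99021 streptavidin peak and 1704 (13.4%, interval 12.79 to 13.99%) in an anti-FLAG peak. Random shifts gave 0.752% and 0.703% on average, and at most 1.04% and 0.974%. The share in a peak of either CHIR99021 list was 7.06% (6.54 to 7.60%) for DMSO peaks of 6 tags. It was 62.7% (58.3 to 66.9%) for 10 to 14 tags and 93.6% (87.2 to 97.4%) for 15 to 19 tags. It was 87.3% (80.7 to 92.3%) for 20 to 49 tags and 63.6% (47.8 to 77.6%) for 50 or more. Among DMSO peaks of at least 10 tags, 68.5% lay in a CHIR99021 streptavidin peak, a value added after seeing the data. With a p score of at least 100 in both lists the share was 59.3%, and with 50% reciprocal overlap, which the short DMSO peaks can hardly meet, 0.0393%. No test of a change in occupancy was possible, since there was 1 library per condition and the lists were called with different shifts. A CHIR99021 region without a DMSO peak is a region without a call, and the unknown DMSO depth gives no limit on binding there.

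Merging the 3 lists gave 33485 regions. Both CHIR99021 lists held 9113 of them. Of these, 1180 (12.9%, interval 12.3 to 13.7%) contained a DMSO peak and 7933 did not, while random shifts gave 0.711% on average and at most 1.09%. Regions of 1 CHIR99021 list contained a DMSO peak in 2.40% of 13545 cases (2.15 to 2.67%). Regions held by anti-FLAG alone numbered 6652, by CHIR99021 streptavidin alone 6568, and by DMSO alone 10827. Regions of all 3 lists had a median length of 1442 bp and regions of both CHIR99021 lists without DMSO one of 1117 bp. The 7933 regions became 3086 when fold enrichment of at least 10 was required and 4541 when a p score of at least 100 was required. The 1180 regions became 237 at that p score, 428 with DMSO peaks of at least 10 tags, 1, counted in anti-FLAG peaks, with 50% reciprocal overlap and 0 at an FDR of at most 1%. That FDR limit left only 14 DMSO peaks and did not always keep the peaks of highest p score. The region on chromosome 17 from 44740356, with a p score of 3100 in all 3 lists, was among those lost.

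The strongest regions of both CHIR99021 lists without a DMSO peak lay on chromosome 2 (167203084 to 167205506), chromosome 10 (21213793 to 21214933) and chromosome 12 (4904580 to 4905680). Their anti-FLAG fold enrichments were 47.96, 68.38 and 86.94, from 335, 298 and 286 tags. Their streptavidin fold enrichments were 59.29, 57.80 and 76.48, with 312, 229 and 211 tags. The next lay on chromosome 18 (25026495 to 25029737), chromosome 2 (13618879 to 13620054), chromosome 11 (5310893 to 5314334), chromosome 17 (21511958 to 21513040, 14438127 to 14439702 and 10271001 to 10273482) and chromosome 9 (22849179 to 22850744). Over these 10 regions fold enrichment ranged from 31.1 to 93.8 by anti-FLAG and from 40.1 to 91.7 by streptavidin.

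The regions that ranked highest over all 3 lists began with chromosome 17 (44740356 to 44743178). It held 2435 anti-FLAG tags, 3111 CHIR99021 streptavidin tags and 3073 DMSO tags. Its leading peaks had fold enrichments of 12.7, 18.26 and 48.82. The medians of these lists were 8.13, 8.56 and 25.81, so the folds are not comparable between lists. The next were chromosome 9 (94559442 to 94563343) and chromosome 18 (35916753 to 35918198). That on chromosome 18 held 535, 532 and 121 tags in that order. The others lay on chromosome 9 (69514870 to 69519669 and 100481430 to 100482996), chromosome 11 (97521750 to 97524728), chromosome 14 (49774585 to 49776164 and 22962757 to 22964162), chromosome 4 (64899369 to 64900379) and chromosome 16 (90436917 to 90438504). On chromosome 14, the region from 22962757 had the highest fold enrichment of the 10 in both CHIR99021 lists, 178.86 and 221.11. Its leading DMSO peak had a fold enrichment of 58.06.

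**Figure D3:**
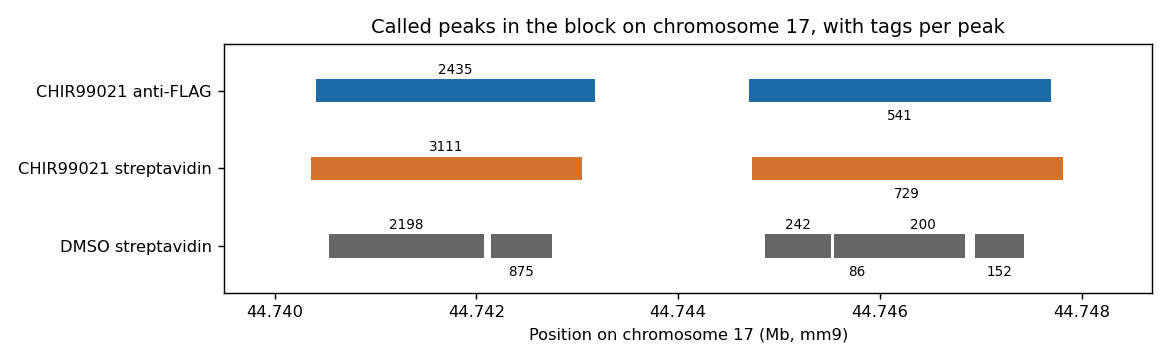
Called peaks of the 3 ChIP libraries (rows) on chromosome 17 between 44740356 and 44747810 (x axis, Mb, mm9), each with its tag count. The leading peaks hold 2435, 3111 and 2198 tags, and the DMSO list splits into 6 peaks what the CHIR99021 lists hold as 2. The DMSO peaks of 86 and 200 tags are separate calls that adjoin at this scale.

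The strongest regions of DMSO alone were of another kind. Of the 10, 8 lay side by side on chromosome Y, between 2898657 and 2902164. The leading one (2899899 to 2900335) had 93 tags and a fold enrichment of 146.34. The others lay on chromosome 2 (22445617 to 22446060) and chromosome 4 (79649062 to 79650995). These had 640 and 2664 tags but fold enrichments of 2.41 and 1.83.

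**Figure D4:**
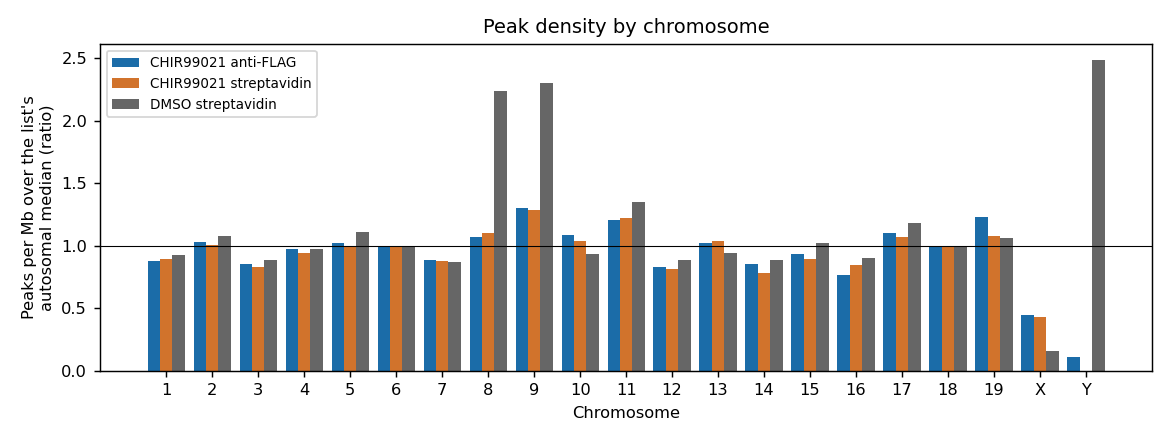
Peaks per Mb on each chromosome (x axis) divided by the median over autosomes of the same list (y axis, ratio), 1 bar per ChIP library. DMSO bars reach 2.24 on chromosome 8 and 2.30 on chromosome 9, and CHIR99021 bars stand at 1.07 and 1.10 on chromosome 8. On chromosome Y the DMSO bar stands at 2.49, from 33 peaks, and the CHIR99021 streptavidin list has no peak. The DMSO peaks themselves set the 2.863 Mb span used there, and 20 of the 33 lie within 35306 bp. The chromosome Y bar is therefore not comparable with those of the autosomes.

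Peaks were spread over the autosomes at a median of 6.52 per Mb for anti-FLAG, 6.57 for CHIR99021 streptavidin and 4.64 for DMSO. In the CHIR99021 lists the densest autosome was chromosome 9, with 8.51 and 8.48 peaks per Mb. In the DMSO list chromosomes 8 and 9 held 1336 and 1286 peaks, 2.24 and 2.30 times the median, and the other 17 autosomes lay between 0.874 and 1.35. Chromosome X lay at 0.443, 0.434 and 0.155 times the median in the anti-FLAG, CHIR99021 streptavidin and DMSO lists. Among DMSO peaks of at least 10 tags, also chosen after seeing the data, it lay at 0.353. Without chromosomes 8 and 9, 14.4% of DMSO peaks lay in a CHIR99021 streptavidin peak.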

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

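Settings of overlap, threshold, ranking and list length were planned, and the 400 bp DMSO windows, the minimum of 10 tags, the chromosome exclusions and all alternatives for chromosome density were added after seeing the data. An FDR of at most 1% left 10417 anti-FLAG, 8832 CHIR99021 streptavidin and 14 DMSO peaks. Fold enrichment of at least 10 left 5279, 5716 and 12540, and a p score of at least 100 left 6779, 6206 and 460. Of anti-FLAG peaks, 57.6% lay in a streptavidin peak, against 54.0% with 50% reciprocal overlap, 52.6% with summits within 200 bp, 59.2% within 1000 bp, 59.9% at an FDR of 1%, 74.2% at a fold of 10, 71.2% at a score of 100 and 63.4% with equal list lengths. Of DMSO peaks, 13.5% lay in a CHIR99021 streptavidin peak. The share was 0.0393% with reciprocal overlap, 10.5% with summits within 200 bp, 15.4% within 1000 bp, 11.3% at an FDR of 5%, 9.59% at a fold of 10 and 12.9% with equal lengths. It was 78.6% of only 14 peaks at an FDR of 1% (0% in anti-FLAG peaks), 59.3% at a score of 100, 68.5% with at least 10 tags and 14.4% without chromosomes 8 and 9. Regions of both CHIR99021 lists without a DMSO peak numbered 3086 at a fold of 10 and 4541 at a score of 100, where fewer peaks enter. Those with a DMSO peak, 1180 in the main setting, moved more: 237 at a score of 100, 428 with at least 10 tags, 0 at an FDR of 1% and, counted in anti-FLAG peaks, 1 with reciprocal overlap and 1346 within 1000 bp. The share of CHIR99021 streptavidin peaks with a DMSO peak, 8.38%, ranged from 0.0314% to 15.5%, and that of anti-FLAG peaks, 8.24%, from 0 to 16.6%. The top 10% of anti-FLAG peaks overlapped in 96.8% by fold and 96.7% by tag count, against 98.4% by p score, and the lowest 10% in 35.9% and 8.77%, against 17.5%. The DMSO density on chromosome 8 was 2.45 times the autosomal median with at least 10 tags, 2.46 outside CHIR99021 peaks and 2.58 at an FDR of 5%. A fold of 10 kept 12540 of 12734 DMSO peaks but only 5716 of 15947 CHIR99021 streptavidin peaks. The loss of DMSO peaks alone therefore cannot account for the drop in their overlap at that limit. Of 63 further shares and density ratios, 16 stayed within the interval of the main value, 22 were higher and 25 lower. Among these, the top 10% of DMSO peaks in CHIR99021 streptavidin peaks went from 37.7% to 9.19% by fold and 57.0% by tag count. The lowest went from 19.2% to 35.1% and 6.59%, the latter an arbitrary cut of peaks tied at 6 tags. Shuffling peaks singly in place of shifting them left each chance share within the range of the shifts. All peaks lay on chromosomes 1 to 19, X and Y, so taking all sequences moved nothing. The alternatives for genomic location, gene lists and motifs were not run. No paired analysis was possible because each group had 1 library. The unknown DMSO depth limits each statement on regions without a DMSO call.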

Other observations

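The 9113 regions of both CHIR99021 lists averaged 3.53 per Mb and gathered in places. The fullest window of 1 Mb, on chromosome 11 (88000001 to 89000000), held 21 of them together with 14 DMSO peaks. Windows on chromosome 2 (20000001 to 21000000) and chromosome 13 (44000001 to 45000000) held 18 and 16. On chromosome X the window from 7000001 to 8000000 held 15. The longest region, on chromosome 19 (5838231 to 5848096), spanned 9866 bp with 525 anti-FLAG tags, 356 CHIR99021 streptavidin tags and 1 DMSO peak of 10 tags. The next longest, on chromosome 9 (61213655 to 61221202) and chromosome 8 (87182825 to 87189728), spanned 7548 and 6904 bp and held no DMSO peak. A few peaks had many tags and low fold enrichment. On chromosome 1 a CHIR99021 streptavidin peak (24618181 to 24623212) had 7407 tags at 1.67-fold and a DMSO peak (24618365 to 24622029) had 6663 tags at 1.49-fold. On chromosome Y, 20 of the 33 DMSO peaks lay between 2867013 and 2902318, where the CHIR99021 lists had none.

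The tests on a loss of binding, on extra copies and on CHIR99021 sites of chromosomes 8 and 9, and those on the block of chromosome 17, were chosen after the result was seen. The others were chosen before. The explanations below are hypotheses from 1 library per condition.

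DMSO peaks were short and few lay in CHIR99021 peaks. Peaks of 20 or more tags lay in a CHIR99021 peak 11.6 times as often as peaks of 6 tags. Many of the small calls may be stacks of few tags called with a 30 bp shift, but this ratio does not single that out. By tag count, the share of anti-FLAG peaks in CHIR99021 streptavidin peaks also fell, from 96.7% in the top 10% to 8.77% in the lowest. The 7.06% of 6-tag DMSO peaks in a CHIR99021 peak lay above the mean chance shares of all DMSO peaks, 0.752% for CHIR99021 streptavidin and 0.703% for anti-FLAG. Neighbouring DMSO summits lay 75 to 250 bp apart in 497 of 12713 pairs (3.91%), 38.0 times the chance number, and these few may be separate calls on the flanks of ordinary fragments or a broader peak split in the call. A loss of binding without the inhibitor would leave CHIR99021 peaks without DMSO peaks and would not account for DMSO peaks elsewhere. It stays open, since 39.71% of the top 10% of CHIR99021 streptavidin peaks held a DMSO peak, and condition and fragment shift cannot be told apart with 1 DMSO list.

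DMSO peaks were dense on chromosomes 8 and 9. Local clusters are argued against, since the lower of the 2 ratios was still 2.43 after the densest 10% of 1 Mb bins of every chromosome were left out, and so are more β-catenin sites on chromosome 8, which reached at most 1.10 times the autosomal median in the CHIR99021 lists, while chromosome 9 was their densest autosome. A shortage of input reads is argued against too: the median fold of 6-tag peaks there was 0.812 times that on the other autosomes (22.44 against 27.65), so by this measure the local background was higher, and 3.36% sat at the genome-wide background value. Extra copies of both chromosomes in part of the DMSO cells stay open: 95.8% of their 10 Mb bins lay above the autosomal median outside CHIR99021 peaks, but the density of the whole chromosomes already implies this, so it does not single out copies among chromosome-wide causes. Extra copies in the input too would also raise the local background, but the 0.812 does not decide the cause. A karyotype was not analysed here. At matched tags the fold ratio of chromosomes 8 and 9 in the CHIR99021 lists was 0.968 and 0.926. On chromosome X it was 1.14 and 1.10 in these lists and 1.06 in the DMSO list.

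A block of 7455 bp on chromosome 17 (44740356 to 44747810) carried 2976 anti-FLAG, 3840 CHIR99021 streptavidin and 3753 DMSO tags, which was 0.327%, 0.488% and 3.47% of all tags in the peaks of each list. These percentages are not comparable between lists, since the peaks held 910311, 787669 and 108183 tags in that order. The input's excess as the whole cause is argued against, because the leading peak's fold was at least 1.56 times its list's median in the 3 lists. An ordinary strong site stays open. The ratio of DMSO to streptavidin tags was 4.31 times the highest of the other 9 strongest shared regions, but short DMSO calls may lower that ratio elsewhere. Per called bp it was 1.27 times the highest (1.23 against 0.967), but short DMSO calls may raise that measure elsewhere. For chromosome 9 from 94559442 the 2 ratios were 0.117 and 0.59. How many tags the short calls miss was not measured, so neither ratio decides. A raised copy number in the input as part of the cause stays open too, since among the 1% of peaks with most tags the leading peak's tags per fold and kb stood at percentile 99.38, 95.6 and 81.89 in the anti-FLAG, CHIR99021 streptavidin and DMSO lists. DNA carried into the ChIP libraries from elsewhere, and binding that does not need the inhibitor, stay open and were not tested.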
